A study of Mus musculus with 6 samples.

How the data were processed

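RNA was measured by sequencing in 6 samples of aortic arch plaque from mice prone to atherosclerosis, 3 from mice given vehicle and 3 from mice given ABT263. The labels' protocols give column extraction with the RNeasy Micro kit and libraries made with the TruSeq RNA Library Prep Kit v2 from 100 to 200 ng of RNA. That kit enriches polyadenylated RNA and does not mark the strand, so reads from a gene and from an antisense partner over its exons could not be told apart. The authors deposited 1 table of raw counts, whole numbers of reads per gene symbol and library. TopHat2 2.0.14, Bowtie2 2.2.6, featureCounts 1.4.6, Subread and the mouse build mm10 are named per the submitters' processing notes, which give them no role or order here. The gene annotation, the strand setting, the rule for reads that map to several places and the read layout are not given in the sources used here. A rule that drops reads shared between genes lowers the counts of paralogs and overlapping genes, and it would do so in every library alike.

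The table held 24062 symbols, none repeated and none a summary line, and each of its 6 count columns carried the title of 1 sample. Groups were taken from the sample titles. Replicates were numbered 1 to 3 within each group in accession order, which only names them, so no pairing was used. The labels do not state that each sample came from a separate animal. The p-values of single genes therefore measure the spread between these samples, which may in part be technical. Library totals ran from 62930547 to 110452098 counts, so that 3 counts, the limit that a count of 0 allows, came to between 0.0272 and 0.0477 CPM. This limit covers counting error only.

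Counts were analysed in R 4.3.3. Genes were kept by the defaults of the edgeR filter filterByExpr (a minimum count of 10 and a minimum total of 15), which left 15222 genes. Library sizes were scaled by TMM. The main test was the quasi-likelihood F-test of edgeR 4.0.16 with its version's default settings, on a model with the group alone, which leaves 4 residual degrees of freedom. Benjamini-Hochberg adjustment ran over all genes tested, with a threshold of 0.05. The standard error given beside a log2 fold change (ABT263 over vehicle) is the absolute fold change divided by the square root of F. Levels are CPM after TMM scaling, as mean ± SD with n = 3 in each group. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run beside it.

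Before the data were examined, 34 gene lists were written for pathways, cell types and RNA quality, and 1 more for sex-linked genes. Of the 34, 32 had at least 5 genes kept and were tested. The 9 mitochondrially encoded genes were not among the symbols analysed, and the erythroid list kept 4 genes. Those 2 lists were not tested. For 4 genes the table used an older symbol (Ctgf for Ccn2, Emr1 for Adgre1, Epb4.2 for Epb42 and Lect1 for Cnmd). Lists were tested with camera of limma on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, which asks whether a list's genes moved more than other genes did. The preset value takes a list's genes as nearly independent. Its p therefore does not measure how far a list as a whole varies between libraries. Camera with the correlation estimated from the data, and fry, were run beside it. The main fry test asks whether a list's genes move, on balance, in 1 direction, and its mixed form whether they change in either. Neither fry test compares the list with other genes. A list score is the mean log2 CPM of the list's genes in a library. Scores and library measures were compared by exact two-sided permutation tests of the difference of means, whose smallest p with 3 against 3 is 0.1, so no call was made from them.

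Named genes followed a rule fixed in advance. Its part on single genes took, per direction, the 12 of largest fold change among called genes whose groups did not overlap, with a mean log2 CPM of at least 1 and no clone or predicted-gene symbol. With no gene called, it took the 12 of smallest unadjusted p under the same conditions, given as values. A further part took the 4 members of smallest p in each list described in detail. The 12 lists described in that way were picked after their values had been seen. The last part listed 17 genes outright. Not every gene these rules selected is given in the text, and those left out are not used here. Genes named to characterise a single library were picked after their values had been seen. Positions came from the GENCODE M21 annotation of GRCm38, the assembly that mm10 denotes. Of 86 genes selected, 85 were matched by symbol, and 21 of them had exons overlapping those of another gene. Counts of such genes are uncertain, as are those of near-identical copies (the Bcl2a1 genes and Ctla2b). Those of the class II genes of the H2 region, which are related in sequence, may be uncertain too.

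The procedure was tested on simulated counts for the same 15222 genes, made from these libraries' means and sizes in 5 simulations with 200 changed genes each. The quasi-likelihood test called 1.21% of 2-fold and 35.4% of 4-fold changes with 3.2 false calls per simulation. DESeq2 called 13.8% and 76.9% with 60.8 false calls per simulation. Camera called the raised list in 5 of 5 simulations and 0 of 155 unchanged lists, in data where genes varied independently of each other. In the real lists the estimated correlation ran from -0.0064 (immediate early and heat shock) to 0.92 (brown adipocyte). The simulated lists therefore do not measure how often camera calls a real list falsely.

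Alternatives were other scalings, no filter, a stricter filter (a CPM of at least 1 in at least 3 samples), the other tools, the white adipocyte or the macrophage score as a covariate, a threshold of 0.1 and each replicate left out in turn. After the data were seen, 3 more were added, namely leaving out vehicle replicate 2 and ABT263 replicate 2 together, removing the ribosomal RNA precursor Rn45s, and the bias-adjusted form of the quasi-likelihood test. Where libraries were left out, lists were tested by camera with the preset correlation only.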

Results

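Bulk RNA was sequenced from plaque of the aortic arch in mice of a strain that develops atherosclerotic lesions on a fat-rich diet. The mice ate a high-fat diet for 12 weeks and a low-fat diet for the last 3 weeks. ABT263 (navitoclax) blocks the survival proteins BCL-2, BCL-xL and BCL-w and is used to remove senescent cells. It was injected into the peritoneum at 100 mg/kg, 1 dose per day, at a time the labels place in week 1 of low-fat feeding without saying for how long. The design compares 3 vehicle libraries with 3 ABT263 libraries, and the title of the series puts the question as one of senescent cells and the repair functions of vascular smooth muscle. Total counts were 67236568, 110452098 and 68100243 in vehicle replicates 1 to 3 and 91688075, 62930547 and 73615839 in ABT263 replicates 1 to 3. Between 16889 and 17419 genes were detected per library. Neither the totals (exact permutation p = 0.8, two-sided) nor the genes detected (exact permutation p = 0.7) separated the groups.

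Xist, the RNA of the inactive X chromosome, stood at 202 to 738 CPM over the 6 libraries, and the Y-linked Ddx3y had 0 counts in all of them, which allows at most 0.0477 CPM. No 2 libraries agreed within sampling noise. Across genes, which are not independent replicates, log2 CPM correlated at r = 0.934 to 0.979 between vehicle libraries and at 0.910 to 0.958 between ABT263 libraries. Between the groups r ran from 0.868 to 0.970, the highest being for vehicle replicate 1 and ABT263 replicate 1, so libraries did not always resemble their own group more. The first principal component held 43.4% of the variance and set ABT263 replicate 2 apart, and the second held 24.9% and set vehicle replicate 2 apart. Rn45s, the ribosomal RNA precursor, took 0.54%, 1.74% and 0.55% of counts in the vehicle libraries and 0.33%, 0.30% and 0.33% in the ABT263 libraries (exact permutation p = 0.1, the smallest possible).

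Among single genes, those of smallest p with groups that did not overlap included Chad, Ibsp, Csf3r and Ikzf1 on the lower side and Ednra, Gabra3 and Rasl10b on the higher side. None of the 24 named by this rule passed the threshold by edgeR, so their values are given without a call. Chad, which encodes the cartilage matrix protein chondroadherin (chromosome 11, 94565047 to 94569127, mm10), stood at 135 ± 39.7 CPM with vehicle and 37.4 ± 11.2 with ABT263 (log2 fold change -1.85, SE 0.32). Ibsp, bone sialoprotein (chromosome 5, 104299171 to 104311469), stood at 115 ± 50.4 and 30.6 ± 7.06 CPM (log2 fold change -1.91, SE 0.37). Csf3r (the receptor for granulocyte colony-stimulating factor), Ikzf1 (a lymphoid transcription factor), Itgal (an integrin of leukocytes), Rhoh (a GTPase of blood cells), Nlrc4 (an inflammasome sensor) and Treml4 (a myeloid receptor) had log2 fold changes of -1.19, -0.94, -1.30, -1.27, -1.30 and -1.95. Prdm1, a regulator of plasma cell differentiation, had -1.27, and March1, a ubiquitin ligase that acts on MHC class II, had -0.82. Trim14 (-1.004) and Ctla2b (-1.09) complete the 12 genes on the lower side. On the higher side, Ednra, the endothelin A receptor of smooth muscle (chromosome 8, 77663031 to 77724464), stood at 1.17 ± 0.438 CPM with vehicle and 5.19 ± 2.32 with ABT263 (log2 fold change 2.15, SE 0.48). Lims2, a focal adhesion protein, had a log2 fold change of 1.34, and Gabra3, a subunit of the GABA-A receptor (chromosome X, 72432681 to 72656848), had 4.22 (SE 0.94), with 7.57, 84.1 and 40.4 CPM in the ABT263 replicates against 1.12 to 3.87 CPM with vehicle. Rasl10b (2.98), Vwc2 (3.60), Tspan11 (3.22), Crispld2 (2.09), Stbd1 (1.63), Wdr92 (1.42), Perp (1.34), Gda (0.996) and Emp2 (0.81) complete the 12 on the higher side. All of the 12 but Gda and Emp2 were highest in ABT263 replicate 2, the library with high adipocyte genes described below. Tspan11, for instance, stood at 4.56, 16.6 and 2.88 CPM in the ABT263 replicates. Without replicate 2 Tspan11 was 2.12 and Stbd1 1.12, while Gda was 1.09. Of these 24 genes, 6 had exons overlapping another gene (among them Ednra, Lims2, Trim14 and Wdr92), so their counts are uncertain.

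**Figure D1:**
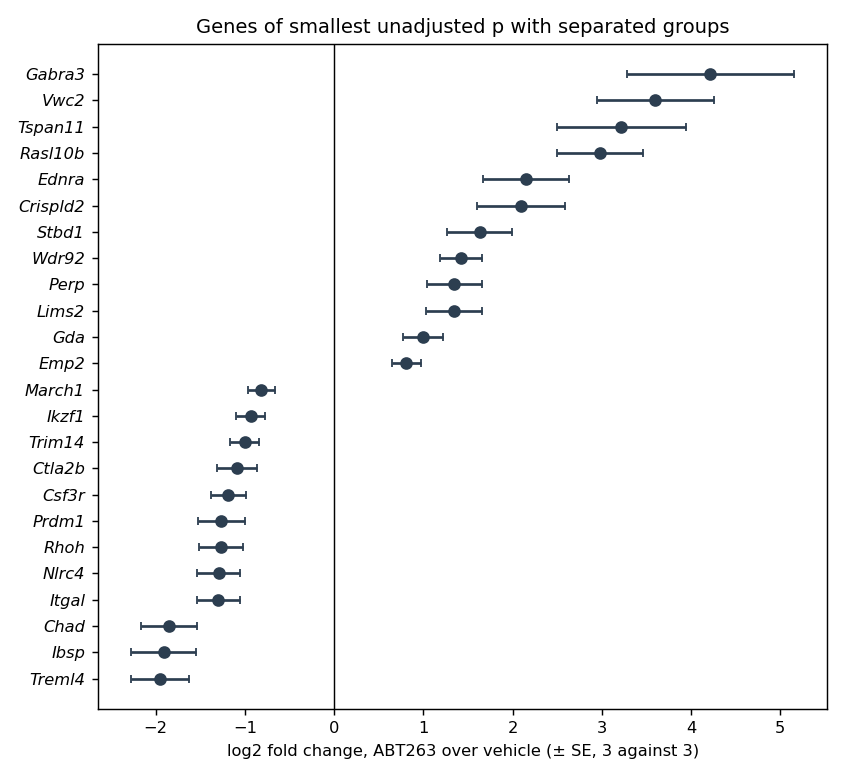
Log2 fold change of ABT263 over vehicle (horizontal axis, bars ± SE, 3 libraries against 3) for the 24 genes of smallest unadjusted p whose groups did not overlap, 12 per direction. Values run from -1.95 for Treml4 to 4.22 for Gabra3, and none passed the adjusted threshold by the quasi-likelihood test.

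The edgeR quasi-likelihood test called 0 of 15222 genes at an adjusted p of 0.05, the smallest adjusted p being 0.592. At an unadjusted p under 0.05 it listed 1276 genes (716 higher and 560 lower with ABT263), where 761 were expected by chance. Groups did not overlap for 1824 genes, 12.0% of those tested against 10% by chance. DESeq2 called 153 genes (69 higher and 84 lower), all 24 genes above among them, and limma-voom called 0, with 1718 and 855 genes at an unadjusted p under 0.05. In simulated data of this design the quasi-likelihood test called 1.21% of 2-fold and 35.4% of 4-fold changes, and DESeq2 made 60.8 false calls per simulation.

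Genes of contractile smooth muscle were higher with ABT263 in replicates 2 and 3 and stood at the vehicle level in replicate 1. All 20 list members had a positive fold change, with a median log2 fold change of 1.55, and the list rose against other genes (camera adjusted p = 2.18e-07). With an estimated correlation the adjusted p = 0.568, and by edgeR no member passed singly or adjusted over the list alone (by DESeq2, Des passed, adjusted p = 0.0195). List scores were 6.39, 6.17 and 6.83 in the vehicle libraries and 6.19, 8.87 and 8.16 in the ABT263 libraries (exact permutation p = 0.3). Myh11, smooth muscle myosin heavy chain (chromosome 16, 14194535 to 14291372), stood at 322 ± 133 CPM with vehicle and 1716 ± 1406 with ABT263, the replicates being 250, 3052 and 1848 CPM (log2 fold change 2.41, SE 0.86, adjusted p = 0.592). Acta2, smooth muscle actin (chromosome 19, 34241090 to 34255590), stood at 1283 ± 226.8 and 3616 ± 2622 CPM (log2 fold change 1.49, SE 0.67). Tagln (transgelin) had a log2 fold change of 1.34 over all libraries, Cnn1 (calponin) 2.16, Synpo2 2.51, Lmod1 1.53 and Des (desmin) 3.62. Without ABT263 replicate 2 Acta2 was 0.88, Tagln 0.74, Myh11 1.71, Cnn1 1.45, Synpo2 1.80, Lmod1 1.19 and Des 1.87. Des, at 3.60, 75.1 and 14.96 CPM with ABT263 and 1.02 to 3.40 with vehicle, was the list member whose groups did not overlap. White adipocyte genes were also high in ABT263 replicate 2, with a score of 8.57 against 1.58 to 2.41 in the 5 other libraries, and skeletal muscle genes in ABT263 replicate 3, with a score of 2.03 against at most -0.35. The contractile list rose in each of the 6 fits that left out 1 library, with camera adjusted p up to 0.000192 at the preset correlation. In a fit with the macrophage score as covariate the log2 fold change of Acta2 was -0.030. Those of Myh11, Tagln, Cnn1, Synpo2, Lmod1 and Des stayed positive. The macrophage score itself differed between the groups without overlap, so this fit takes up part of the group difference.

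Genes of the fibrous cap matrix did not pass (20 of 24 members with a positive fold change, median 0.35, camera adjusted p = 0.153). The list did pass upward without vehicle replicate 3 (adjusted p = 0.00909), ABT263 replicate 1 (0.00500) or ABT263 replicate 2 (0.0207), and its direction turned without ABT263 replicate 3 (0.177). Col1a1 had a log2 fold change of 0.11 (SE 0.57), Col3a1 0.68 (SE 0.51), Postn (periostin) 0.70, Dcn (decorin) 0.57, Fmod (fibromodulin) -0.69 and Mfap4, a microfibril protein, 2.13. Col1a1 was -0.079 without vehicle replicate 2 and -0.68 without ABT263 replicate 3. Over the fits that left out 1 library, Col3a1 ranged from 0.054 to 0.99, Postn from 0.42 to 1.01, Dcn from 0.27 to 0.85 and Fmod from -1.06 to -0.33. Markers of modulated smooth muscle went both ways (8 positive and 6 negative, camera adjusted p = 0.601), and Ibsp was the 1 of 14 that passed adjusted over the list alone. The list passed downward without ABT263 replicate 3 (0.0499) and turned upward without ABT263 replicate 2 (0.0622) and without vehicle replicate 2 and ABT263 replicate 2 together (0.111). In this list the median (0.23) was positive and the mean (-0.039) and the test direction were negative. Matrix-degrading enzymes and inhibitors (median -0.064, mean 0.13, camera adjusted p = 0.968, a direction that turned with RLE size factors) and the PDGF and TGF-beta growth factors (median 0.14, camera adjusted p = 0.712) did not pass either. Adventitial fibroblast markers rose (10 of 10 members positive, median 1.77, camera adjusted p = 0.00118, adjusted p = 0.568 with an estimated correlation). Their score was 5.14 to 5.47 with vehicle and 5.56, 8.45 and 6.13 with ABT263 (exact permutation p = 0.1), so fibroblast and fat genes were highest in the same library. Without vehicle replicate 2 and ABT263 replicate 2 together the fibroblast list no longer passed (adjusted p = 0.0854).

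Genes of T cells, B cells, neutrophils and macrophages were lower in every ABT263 library by their list scores. T cell genes fell as a list, with 12 of 12 members negative, a median log2 fold change of -1.10 and a camera adjusted p of 1.23e-08 (adjusted p = 0.551 with an estimated correlation). Scores were 4.05, 4.40 and 4.25 with vehicle and 2.29, 3.73 and 2.75 with ABT263 (exact permutation p = 0.1). B cell genes fell too, 10 of 10 negative, median -2.15, camera adjusted p = 1.23e-08 (adjusted p = 0.551 with an estimated correlation), with scores of 1.72, 1.78 and 3.47 against -0.42, 0.92 and 0.61. Members that passed by edgeR adjusted over the list alone, and not over all genes, included Cd79a, part of the B cell receptor (chromosome 7, 24897381 to 24902197; 13.2 ± 9.58 against 2.31 ± 0.926 CPM, log2 fold change -2.51, SE 0.61), Fcer2a (-2.76) and Cd79b (-2.06). By DESeq2 over all genes, Cd79a (adjusted p = 0.00890) and Fcer2a (0.0194) passed and Cd79b (0.0536) did not. The T cell receptor genes Cd3g and Cd3e had log2 fold changes of -1.88 and -1.51, Cd2 -1.15 and Cd5 -1.10, each with groups that did not overlap and none past the threshold. Neutrophil genes fell (8 of 8 negative, median -1.43, camera adjusted p = 2.72e-05, adjusted p = 0.551 with an estimated correlation), with scores of 3.04, 3.37 and 2.38 against 2.36, 1.33 and -0.36. Among them Camp, an antimicrobial peptide gene, had a log2 fold change of -2.69, S100a8 -1.44, S100a9 -1.43 and Elane, neutrophil elastase, -2.22 at no more than 0.334 CPM. Rn45s, given above, was lower in the same libraries as these lists.

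Macrophage genes fell as well, with a smaller median. The list had 14 of 15 members negative, a median of -0.71 and a camera adjusted p of 6.95e-06 (adjusted p = 0.551 with an estimated correlation), and its scores were 8.62, 8.74 and 8.15 with vehicle and 8.05, 7.63 and 7.94 with ABT263. The complement genes C1qb (chromosome 4, 136880129 to 136886187) and C1qc had log2 fold changes of -1.25 (SE 0.42) and -1.23 (SE 0.39), C1qb standing at 2519 ± 1020.2 and 1062 ± 289 CPM. Csf1r, the receptor for the macrophage growth factor, had -0.71, and Fcgr1, an Fc receptor, -1.78, or -0.74 without vehicle replicate 2 (62.4, 232 and 49.4 CPM with vehicle). Cd68 (-0.68) and Lgals3 (-0.71), macrophage genes of the plaque, had groups that overlapped. Without ABT263 replicate 2 both were -0.33, and Csf1r was -0.63. Foam cell lipid-handling genes fell (17 of 18 negative, median -0.63, camera adjusted p = 5.73e-05, adjusted p = 0.568 with an estimated correlation). Their scores overlapped, at 10.82, 9.72 and 10.16 with vehicle and 9.90, 9.03 and 10.04 with ABT263 (exact permutation p = 0.4). Apoe, at 16345 ± 5109 CPM with vehicle and 8284 ± 2942 with ABT263, had a log2 fold change of -0.98 (SE 0.54), Trem2 -0.71, Fabp5 -0.68 and Nr1h3, the sterol-sensing receptor LXR-alpha, -0.69. In the fit without ABT263 replicate 2, Apoe was -0.89, Trem2 -0.40, Fabp5 -0.44 and Nr1h3 -0.73. T cell, B cell, neutrophil, macrophage, foam cell and class II lists passed in each of the 6 fits that left out 1 library. Those fits used camera with the preset correlation, so they cannot show a change beyond the correlation between a list's genes. Dendritic cell (camera adjusted p = 0.0320), thymocyte (0.0402) and platelet genes (0.00748) also fell, with adjusted p = 0.568, 0.592 and 0.568 with an estimated correlation. Their scores overlapped between the groups, and the highest thymocyte score was that of ABT263 replicate 2 (3.61 against 1.92 to 3.39 with vehicle). The dendritic cell call was lost without vehicle replicate 2 (adjusted p = 0.0979), vehicle replicate 3 (0.250) or ABT263 replicate 1 (0.473), and the platelet call without vehicle replicate 3 (0.374) or ABT263 replicate 3 (0.128). The thymocyte call was lost without vehicle replicate 1 (0.261), vehicle replicate 3 (0.196), ABT263 replicate 1 (0.393) or ABT263 replicate 3 (0.216).

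**Figure D2:**
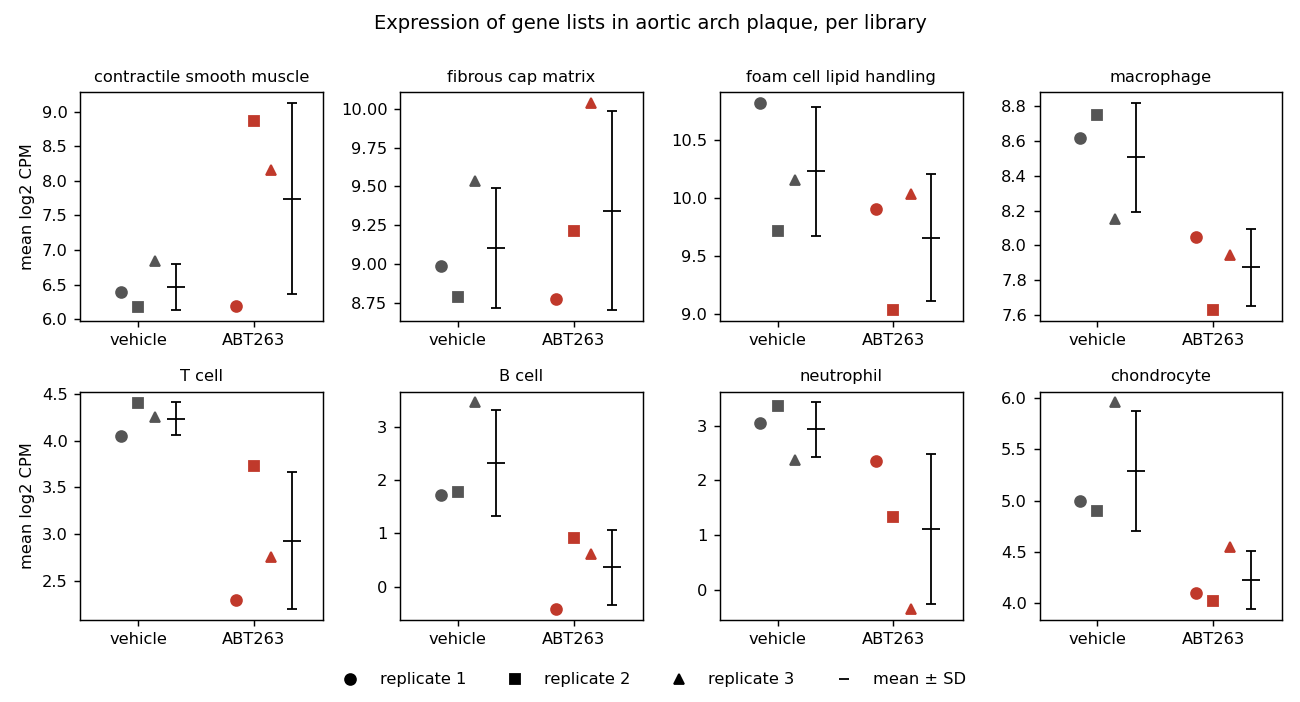
List score, the mean log2 CPM of a list's genes (vertical axis), in each vehicle and ABT263 library for 8 gene lists, with the group mean ± SD (n = 3). T cell scores lay between 4.05 and 4.40 with vehicle and between 2.29 and 3.73 with ABT263, and contractile scores were 8.87 and 8.16 in ABT263 replicates 2 and 3 and at most 6.83 in the 4 other libraries.

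Antigen presentation genes of MHC class II fell (10 of 10 negative, median -2.64, camera adjusted p = 1.61e-05, adjusted p = 0.568 with an estimated correlation), and their highest score was that of vehicle replicate 2. Scores were 4.87, 8.63 and 6.48 with vehicle and 4.39, 5.07 and 5.06 with ABT263 (exact permutation p = 0.3). H2-Aa stood at 230, 6373 and 847 CPM with vehicle and 272, 370 and 337 with ABT263 (log2 fold change -2.93, SE 1.14). H2-Oa (-2.86), H2-Ob (-2.57) and H2-DMb2 (-2.36) were lower as well, H2-DMb2 being the 1 member that passed adjusted over the list alone. Without vehicle replicate 2, H2-Aa was -0.72, H2-Oa -1.72, H2-Ob -2.03 and H2-DMb2 -1.92. Interferon response genes (13 of 16 negative, median -1.63, camera adjusted p = 0.0128) and inflammatory cytokines and chemokines (15 of 18 negative, median -0.86, camera adjusted p = 0.000152) fell, with adjusted p = 0.602 and 0.568 with an estimated correlation. Interferon scores were 2.31, 6.35 and 3.43 against 2.59, 4.10 and 2.51, and without vehicle replicate 2 the direction turned (adjusted p = 0.921). The interferon call was also lost without ABT263 replicate 1 (0.0860) or ABT263 replicate 3 (0.231) and without vehicle replicate 2 and ABT263 replicate 2 together (0.111). The cytokine call was lost without vehicle replicate 2 (adjusted p = 0.0572) and without the same pair (0.755). Tnf, tumour necrosis factor, stood at 6.42, 35.8 and 4.49 CPM with vehicle and 5.04, 1.75 and 2.65 with ABT263 (log2 fold change -2.30, SE 0.88, or -0.79 without vehicle replicate 2).

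Cartilage genes fell as a list and were lower in every ABT263 library (9 of 9 members negative, median -0.87, camera adjusted p = 8.59e-05, adjusted p = 0.551 with an estimated correlation). Scores were 4.998, 4.90 and 5.96 with vehicle and 4.10, 4.02 and 4.55 with ABT263 (exact permutation p = 0.1). Chad, Col2a1 and Col10a1 passed adjusted over the list alone. Col2a1, the main collagen of cartilage (chromosome 15, 97975602 to 98004695), stood at 1218 ± 483 and 524 ± 68.8 CPM (log2 fold change -1.22, SE 0.35). Col10a1, the collagen of hypertrophic cartilage, stood at 13.9, 10.6 and 169 CPM with vehicle and 3.79, 5.68 and 3.32 with ABT263 (log2 fold change -3.92), and Lect1, which encodes chondromodulin, had -1.18. Without vehicle replicate 3, Col10a1 was -1.53 and Col2a1 -0.85. The call was kept in each of the 6 fits that left out 1 library (camera adjusted p up to 0.00210 at the preset correlation).

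Senescence genes and their secretory products did not move as a list (9 positive and 11 negative, camera adjusted p = 0.955), and the median (-0.11) differed in sign from the mean (0.15) and the upward test direction. Cdkn2a, a senescence marker whose products include p16 (chromosome 4, 89274471 to 89294653), stood at 6.51, 9.25 and 5.28 CPM with vehicle and 12.9, 2.19 and 3.55 with ABT263 (log2 fold change -0.17, SE 0.67). Counts are per gene symbol, so they do not measure p16 alone. Cdkn1a, which encodes p21, had -0.21 (SE 0.38). Both values turned positive without vehicle replicate 2 and ABT263 replicate 2 together (0.48 and 0.37), and the list then passed upward (adjusted p = 0.0290), as it did without ABT263 replicate 2 alone (0.0249). Its direction turned without vehicle replicate 3, ABT263 replicate 1 or ABT263 replicate 3 (adjusted p = 0.870, 0.393 and 0.654). Igfbp3, an insulin-like growth factor binding protein (chromosome 11, 7206086 to 7213923), stood at 37.2 ± 27.6 and 54.8 ± 27.6 CPM (log2 fold change 0.56, SE 0.68). Mmp3, stromelysin, had 1.996 (SE 0.71), with 149, 69.9 and 420 CPM against 28.4 to 83.3. Over the fits that left out 1 library, Igfbp3 ranged from 0.10 to 1.24 and Mmp3 from 1.03 to 2.47, both lowest without ABT263 replicate 3. Insulin-like growth factor genes rose (12 of 15 positive, median 0.56, camera adjusted p = 0.0402, adjusted p = 0.592 with an estimated correlation), led by Igfbp5 (5.52), Igfbp6 (4.70), Igfbp4 (1.34) and Irs1 (1.12). Igfbp5 stood at 12.1, 1509.5 and 53.6 CPM, Igfbp6 at 8.40, 134 and 3.58 and Igfbp4 at 502, 1027 and 253 in the ABT263 replicates, each highest in replicate 2, the library with the high adipocyte score. Without that library the log2 fold changes were 1.53, 1.69 and 0.70, and that of Irs1 was 0.61. That call was lost without vehicle replicate 2 (adjusted p = 0.551), ABT263 replicate 2 (0.108) or ABT263 replicate 3 (0.156), and without vehicle replicate 2 and ABT263 replicate 2 together (0.903).

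Genes of the BCL-2 family, to which the targets of ABT263 belong, fell as a list (13 of 17 negative, median -0.47, camera adjusted p = 0.00107, adjusted p = 0.568 with an estimated correlation). The members with the smallest p were not the targets. They were Bmf (-0.83) and Bcl2l11 (-0.78), which promote cell death, and the survival genes Bcl2a1b (-1.29) and Bcl2a1a (-2.25) of blood cells, whose reads near-identical copies can share. Without vehicle replicate 2 the last 2 were -0.90 and -0.99. Bcl2l11, which encodes BIM, stood at 59.8 ± 3.22 CPM with vehicle and 34.7 ± 7.19 with ABT263. Among the targets, Bcl2 had a log2 fold change of 0.09 (SE 0.25), Bcl2l1 -0.34 (SE 0.23) and Bcl2l2 0.30 (SE 0.17). Bcl2 and Bcl2l2 have exons overlapping another gene, so their counts are uncertain. The list no longer passed without vehicle replicate 2 (adjusted p = 0.0720) or without vehicle replicate 2 and ABT263 replicate 2 together (0.362). BCL-2 family scores were 5.09, 5.66 and 5.06 with vehicle and 5.02, 4.50 and 4.84 with ABT263. They were lower in every ABT263 library, by little in replicate 1, as were the T cell, B cell, neutrophil and macrophage scores. Targets of p53 did not move as a list (median 0.031 and mean 0.020, with a downward test direction, camera adjusted p = 0.968). Proliferation genes fell by little (17 of 20 negative, median -0.15, camera adjusted p = 0.0402, adjusted p = 0.745 with an estimated correlation), and Mki67 stood at 45.0 ± 7.18 and 45.0 ± 21.7 CPM. Their direction turned without ABT263 replicate 2 (adjusted p = 0.0249) and without vehicle replicate 2 and ABT263 replicate 2 together (6.48e-06). The call was also lost without vehicle replicate 2 alone (0.750). Cholesterol synthesis genes rose by little (14 of 17 positive, median 0.38, camera adjusted p = 0.0326, adjusted p = 0.568 with an estimated correlation), a call lost without vehicle replicate 2 (0.199), vehicle replicate 3 (0.126) or ABT263 replicate 2 (0.347), and without vehicle replicate 2 and ABT263 replicate 2 together (0.761).

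Markers of tissue around the vessel set single libraries apart. White and brown adipocyte genes rose (median 6.23 and 5.22, camera adjusted p = 0.00917 and 0.0471, adjusted p = 0.592 for both with an estimated correlation), with the rise in ABT263 replicate 2. Adipoq, the adipocyte hormone adiponectin, stood at 356 CPM there and at 0.0960 to 0.510 in the 5 other libraries, and Ucp1, the uncoupling protein of brown fat, at 80.2 CPM and at most 0.224. Without that library the white and brown adipocyte lists had adjusted p = 0.860 and 0.564 and the direction of both turned. Both calls were also lost without vehicle replicate 2 (adjusted p = 0.0572 and 0.172) and without vehicle replicate 2 and ABT263 replicate 2 together (0.481 and 0.504). Skeletal muscle genes rose (10 of 10 positive, median 2.17, camera adjusted p = 0.00107, adjusted p = 0.568 with an estimated correlation), and their score was 2.03 in ABT263 replicate 3 and at most -0.35 elsewhere. That call was lost without ABT263 replicate 3 (adjusted p = 0.216). Endothelial (camera adjusted p = 0.204), lymphatic endothelial (0.113), cardiac muscle (0.236), Schwann cell (0.159) and immediate early and heat shock genes (0.159) did not pass. Without ABT263 replicate 2, immediate early and heat shock genes passed upward (adjusted p = 0.0212) and Schwann cell genes downward (0.0213). Endothelial genes passed upward without vehicle replicate 3 (0.0140) or ABT263 replicate 3 (0.0192) and turned downward without vehicle replicate 2 (0.172) or ABT263 replicate 1 (0.631), and lymphatic endothelial genes passed upward without ABT263 replicate 3 (0.00880). The 4 erythroid genes had scores of 4.37, 3.90 and 4.27 with vehicle and 6.05, 5.66 and 1.33 with ABT263 (exact permutation p = 1).

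**Figure D3:**
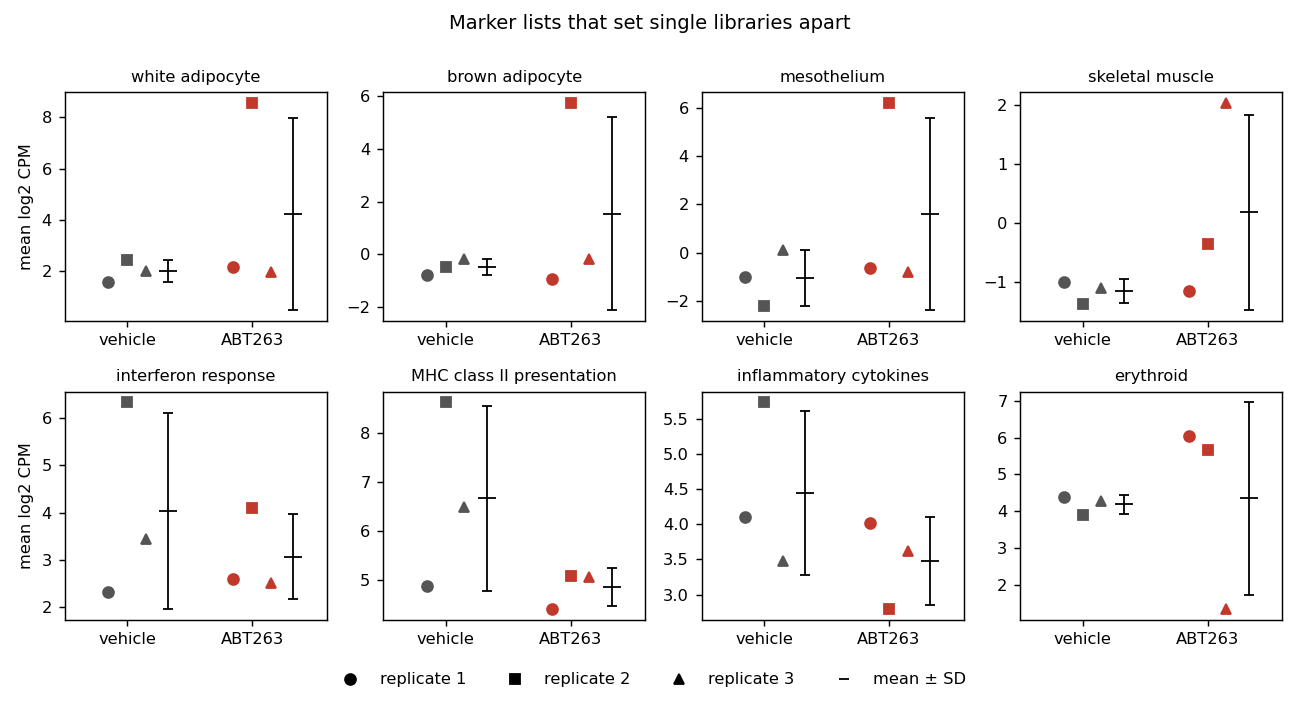
List score, the mean log2 CPM of a list's genes (vertical axis), in each library for 8 marker lists, with the group mean ± SD (n = 3). White adipocyte scores were 8.57 in ABT263 replicate 2 and at most 2.41 elsewhere, and interferon scores were 6.35 in vehicle replicate 2 and at most 4.10 elsewhere.

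Over the 34 lists, 32 were tested and 21 passed (7 higher and 14 lower) with the preset correlation. None passed with an estimated correlation or by either fry test, the smallest adjusted p being 0.551 and, for the directional fry test, 0.423. By edgeR, 9 list members in 4 lists passed adjusted over the list alone and 0 over all genes, and by DESeq2 15 members in 11 lists passed over all genes. Scores did not overlap between the groups for 7 lists, 1 higher and 6 lower.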

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

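Leaving out vehicle replicate 2 and ABT263 replicate 2 together, removing Rn45s and the bias-adjusted quasi-likelihood test were chosen after the data were seen. The other alternatives were fixed before. The count of 0 called genes was the same under each scaling, filter, covariate, leave-one-out fit and added alternative, at an adjusted p of 0.1 and by limma-voom with or without quality weights. It moved only with DESeq2, to 153 genes, 69 higher and 84 lower, and the cause was not tested. Genes at an unadjusted p under 0.05 numbered 1276 and ranged from 653 (without ABT263 replicate 2) to 1867 (without ABT263 replicate 1) in the fits that left out 1 library. They numbered 805 without vehicle replicate 1, 2012 with quality weights, 673 with the white adipocyte covariate and 305 with the macrophage covariate. The count of lists past the threshold, 21 in the main test, was 0 with an estimated correlation and 0 by fry, which use the correlation between the genes of a list. It was 12 to 21 with 1 library left out (12 without vehicle replicate 2). It was 21 with RLE size factors, 18 with the stricter filter, 21 without Rn45s and 16 without vehicle replicate 2 and ABT263 replicate 2. These counts take either direction and can hold lists not called in the main test. The 16 include proliferation genes, which had turned upward, so the counts overstate how many of the first calls were kept. The stricter filter left 28 lists to test, without the brown adipocyte and skeletal muscle lists, and ended 1 call, that of thymocyte genes (adjusted p = 0.1004). Of the 21 lists called in the main test, 9 passed in the same direction in each leave-one-out fit (2 higher and 7 lower), and 8 of these also without both libraries. These fits kept the preset correlation. They therefore do not show that a call holds beyond the correlation between a list's genes. The direction turned under some alternative in 4 called lists (proliferation, interferon, white and brown adipocyte) and in 7 of the 11 not called. Of those 11, 3 passed without vehicle replicate 2 and ABT263 replicate 2, among them immediate early and heat shock (adjusted p = 0.00754) and Schwann cell genes (0.0496).

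Of 85 genes selected to be named, 65 kept the sign of their fold change under each of the 19 alternatives in which they were tested (the stricter filter left out Elane and H2-Oa), and 34 passed by DESeq2 alone. In 14 the sign turned with the macrophage covariate alone. The macrophage score itself differed between the groups without overlap, so this fit takes up part of the group difference. With it, the log2 fold changes were Acta2 -0.030, Postn -0.0072, Irs1 -0.050, Igfbp3 -0.80, Igfbp5 -1.31, Bcl2 -0.47, Col1a1 -0.35, Tnf 0.57, Bcl2a1a 0.22, Bcl2a1b 0.097, Fcgr1 0.020, S100a8 0.26, S100a9 0.42, Trem2 0.094, Cd68 0.26, Lgals3 0.74, Cdkn1a 0.59 and Cdkn2a 1.20. With the white adipocyte covariate, Cdkn1a was 0.026 and Cdkn2a 0.21. Without vehicle replicate 2 and ABT263 replicate 2, Cdkn1a was 0.37, Cdkn2a 0.48 and Bcl2 -0.096. Mki67, at 0.00, was -0.0076 with RLE size factors, -0.0080 with upper-quartile scaling, -0.0076 with DESeq2, -0.0022 with the stricter filter and -0.12 with limma-voom. Col1a1 was -0.079 with limma-voom, Cdkn1a 0.045 with quality weights and Xist 0.012 with library size alone. With 1 library left out, Bcl2 ranged from -0.037 to 0.28, Cdkn1a from -0.53 to 0.095, Cdkn2a from -1.29 to 0.23, Col1a1 from -0.68 to 0.43, Mki67 from -0.37 to 0.33 and Xist from -0.45 to 0.30. The cause of these turns was not tested beyond the libraries and covariates named. The scalings moved the median fold change of all genes by at most 0.091 on the log2 scale.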

Other observations

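The tests of the 3 patterns weighed here were chosen after the values they concern had been seen, and the elastic fibre, mesothelium and both lymph node lists were written then. The counts over other splits of the samples were planned. Several genes known to be induced by interferon were highest in vehicle replicate 2. Cxcl9, a chemokine that attracts T cells, stood at 422 CPM there and at 0.0930 to 3.79 in the 5 other libraries, Cxcl10 at 93.6 and at most 1.65, and Irf7, a regulator of interferon genes, at 326 and at most 37.9. Cd74, the invariant chain of MHC class II, stood at 13491 CPM against 537 and 1850 in the other vehicle libraries and 757 to 808 with ABT263. Rsad2 and Isg15, also induced by interferon, were not highest there. Rsad2 stood at 41.4 CPM in vehicle replicate 2 and 85.3 and 98.3 in ABT263 replicates 1 and 2, and Isg15 at 71.9 CPM in vehicle replicate 2, 14.1 and 12.8 in the other vehicle libraries and 79.4, 32.3 and 6.24 with ABT263.

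Genes of red cells and of skeletal muscle set ABT263 libraries apart from each other. Alas2, the enzyme that starts haem synthesis in red cell precursors, stood at 977, 697 and 762 CPM with vehicle and at 3207, 1841 and 145 CPM with ABT263. The globin genes Hbb-bs and Hbb-bt were listed at 0 in all 6 libraries and Hba-a1 at 5 counts or fewer, although Alas2 was abundant. The sources used here do not say how reads shared between globin copies were counted, so these zeros give no measure of blood. Acta1, skeletal muscle actin, stood at 12.5 CPM in ABT263 replicate 3 and at 0.742 to 1.33 elsewhere. Mzb1, a gene of antibody-secreting cells, stood at 1.31, 3.12 and 1.58 CPM with vehicle and 0.155, 0.252 and 0.351 with ABT263.

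The 6 samples allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 0 called genes (highest other split 0), 1276 genes at an unadjusted p under 0.05 (highest other 1606) and 21 lists past the threshold (other splits 9 to 19). Counts as large were given by 10, 3 and 1 of the splits, the real one included.

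Contractile smooth muscle genes were higher in ABT263 replicates 2 and 3, by a mean score of 2.05 over the vehicle mean, and not in replicate 1. A lower share of macrophages would raise other cell types alike. Endothelial, T cell, B cell and neutrophil scores changed by a mean of -1.23 (SE 0.40, lists and libraries taken as independent) in these libraries. The T cell, B cell and neutrophil lists had already been seen to be lower in every ABT263 library. Endothelial scores were 6.92 and 6.29 in replicates 2 and 3 (vehicle 6.53 ± 1.18), and adventitial fibroblast scores 8.45 and 6.13 (vehicle 5.28 ± 0.17). The mean therefore cannot decide on a lower share of leukocytes together, which stays open. Perivascular fat as the source is argued against in replicate 3, where the white adipocyte score differed by -0.46 from the highest vehicle score, but skeletal muscle genes were high in that library (score 2.03 against at most -0.35 elsewhere) and what that tissue adds was not tested. In replicate 2, where that score was 6.16 above, fat and a change in smooth muscle cannot be told apart, since the muscle content of the fat was not measured. More media in the dissected piece also stays open. The mean score of 5 elastic fibre genes, which smooth muscle of the media makes, was higher by 0.76 against a vehicle SD of 0.70. Scores were 9.85 and 9.93 in replicates 2 and 3 and up to 9.79 with vehicle. Mfap4, already seen to be high there (320 and 253 CPM, 36.4 to 53.8 with vehicle), is among these genes. The others were not scored without it, so a rise of the group as a whole is not shown. A response to ABT263 in some of the treated samples remains a hypothesis that these data may fit but do not test.

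T cell, B cell, neutrophil and macrophage scores lay lower in all 3 ABT263 libraries than in every vehicle library, whereas dendritic cell and thymocyte scores overlapped. Erythroid genes argue against residual blood in the vehicle samples as the source for replicates 1 and 2, whose mean erythroid score (4 genes) lay 1.48 above the highest vehicle score. Their platelet scores (1.92 and 2.198), however, lay within the vehicle range and below the vehicle mean of 2.51. In replicate 3 the erythroid and platelet scores, 2 of 2, were the lowest of the 6 libraries, so less blood may contribute there. Both readings assume that ABT263 left the make-up of blood, platelets included, unchanged, which was not tested. Dilution by smooth muscle is argued against in replicate 1, where the contractile score was at the vehicle level and the T cell score differed by -1.76 from the lowest vehicle score. In replicates 2 and 3 it stays open, since T cell and B cell scores changed there by a mean of -0.078 and -1.04 beyond the macrophage score. The mean in replicate 2 held opposite values, 0.37 for T cells and -0.53 for B cells. In replicate 3 the T cell value (-0.93, vehicle SD 0.34) went against dilution but the B cell value (-1.15) lay within the vehicle SD of 1.30. Lymph node carried into the vehicle samples stays open as well: a first list of lymph node genes (7 tested, 2 of them also in the B cell list) was higher in 3 of 3 vehicle libraries than in all ABT263 libraries, and a narrower list of stroma genes, drawn up after that outcome because lymphocytes share the first list's genes, was so in 1 of 3 with only 3 genes tested, so lymph node cannot be told apart from fewer leukocytes in treated plaque, which no test here addressed.

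Fat genes were high in ABT263 replicate 2 alone, with Adipoq at 356 and Plin1, which coats fat droplets, at 282 CPM. Mesothelium lines the outside of tissue in the chest, and 5 of its genes, of which 1 reached 1 CPM in the vehicle mean and none is in another list, had a score 6.09 above that of any other library, with Msln (mesothelin) at 153 CPM against at most 0.527. These values are consistent with fat and mesothelium carried into this sample, a hypothesis found and tested in the same library, and a response to ABT263 in this sample alone was not tested.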
